A study of Arabidopsis thaliana with 15 samples.

How the data were processed

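Gene expression was measured on Affymetrix arrays in Arabidopsis thaliana seedlings of the ecotype Columbia, 7 days old, in 5 groups of 3 biological replicates. Per the labels' protocols, seeds germinated on semi-solid ATS medium that contained 30% deuterium oxide (D2O) or none, under continuous light; seedlings were frozen in liquid nitrogen, total RNA was purified with a Qiagen plant kit, and biotin-labelled cRNA was made by the manufacturer's standard protocol. The groups, from the titles and the series design, were growth on H2O medium (H2O), growth on D2O medium (D2O), and moves for 4 h from H2O to H2O medium (HH), from H2O to D2O medium (HD) and from D2O to H2O medium (DH). The deposited table holds log2 expression values per probe set, which the authors made with RMA, per the submitters' processing notes; the software, its version and its settings are not given in the sources used here. The notes do not state the scale in words, and the range and near-equal medians of the values were checked to be those of log2 values. They were used as deposited, without further normalization. The number of arrays, 3 per group, limits the precision.

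The table held 22810 probe sets, of which 64 Affymetrix controls were left out and 22746 tested. The probe annotation used here names exactly 1 gene for 13513 of these, several for 503 and none for 8730; symbols were given for 1580 and a locus identifier alone for 11933. Counts cover all tested probe sets, and names come from probe sets with 1 gene. No genome build is named for the annotation, so no coordinates are given.

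A linear model with 1 mean per group was fitted over all 15 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, each comparison was tested two-sided, and p was adjusted by the Benjamini-Hochberg method over the 22746 probe sets, with calls at adjusted p under 0.05. There were 7 comparisons: D2O over H2O, HD over HH, DH over HH, DH over D2O, HH over H2O and the interaction terms recovery beyond transfer, (DH minus D2O) minus (HH minus H2O), and long-term minus short-term, (D2O minus H2O) minus (HD minus HH). Standard errors are those of the moderated fit. For overlaps, the count by chance is the product of both numbers of calls divided by the number of probe sets.

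The comparisons, tests, 27 gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The rule names, for D2O over H2O, HD over HH and DH over HH, the 10 largest rises and the 10 largest falls among called probe sets with 1 gene, non-overlapping groups (for interactions without this condition) and a brighter group mean above the median of all probe sets (7.67), and for the other comparisons the 5 largest each way; to these come up to 2 called members each way per list. Further called list members and the members of symbol groups are named as examples picked after their values were seen. Of 513 list members 84 were measured by a probe set named in the annotation, and 13 lists had at least 3 such members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison; each was also tested with an estimated correlation and with fry. These lists, with the members measured of those chosen, were abscisic acid and dehydration (5 of 25), auxin early response (6 of 19), cell division (3 of 25), the unfolded protein response of the endoplasmic reticulum (4 of 16), expansins and xyloglucan enzymes (11 of 24), flavonoid and anthocyanin (3 of 20), heat shock and protein folding (6 of 24), jasmonate (3 of 23), low oxygen and fermentation (3 of 15), photosynthesis (10 of 48), root hair (3 of 16), touch and rapid stress response (4 of 18), and tubulins (9 of 22). Counts of list members below refer to the measured ones. In each comparison where a list was called, its median, its mean and its test had the same sign. Lists with 1 or 2 measured members are reported by member: chlorophyll synthesis, circadian clock, ethylene, glucosinolate, oxidative stress, ribosome, root tissue, salicylic acid and defence, seed reserve and sugar starvation. The remaining 4 lists had 0 members named by this annotation and were not analysed here. A further 23 groups of genes were formed from the symbols after the annotation and array summaries, but before any comparison, had been seen, and were tested the same way. The estimated correlation lay below the preset 0.01 for the touch list (-0.0125), U-box ubiquitin ligases (-0.0273), calmodulin-like proteins (-0.0851) and beta-glucosidases (-0.0113). Where their calls ended with the estimate, a higher correlation between members was thus not the reason.

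RNA quality was read from the 3' minus 5' difference of the GAPDH, actin and ubiquitin control probe sets and compared between groups with exact permutation tests. The method was tested on simulated data: changes added in HD, to 66 or 67 of 22746 probe sets for each size, were recovered in HD over HH at 64.2%, 95.5% and 100% for log2 sizes of 0.5, 1 and 2, with 8 false calls. In the long-term minus short-term term the shares were 31.3%, 94.0% and 100%, with 3 false calls. A shift of 0.5 added to 33 genes of 1 symbol group, the plastid-encoded photosynthesis subunits, was called, and 0 of 245 other list tests were. The simulated errors were independent between probe sets, whereas that group had an estimated correlation of 0.406 in the measured data. The simulation therefore does not show how often lists of correlated genes are falsely called at the preset correlation.

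Alternatives, tried one at a time, were replicate number as a block, a variance trend together with robust moderation, leaving out the lowest 40% of probe sets by mean, quantile and cyclic loess normalization, array weights, only the groups compared, only probe sets with 1 gene, a 2-fold minimum, adjusted p under 0.01, an estimated correlation, fry in one or either direction, and each array left out in turn. Where that left 2 arrays in a group, the variance was pooled over the other groups. Added after seeing the data were the removal of D2O replicate 1 and HD replicate 1 together, which had low correlations within their groups, and the replicate number as a block within H2O and D2O alone. The labels state no shared batch, but deviations from the group means were correlated in all 3 same-numbered pairs of H2O and D2O (r 0.197 to 0.429). These numbers may therefore pair the arrays. Differently numbered arrays of other groups reached similar values, such as 0.393 for D2O replicate 2 and HD replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.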

Results

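Transcript levels were measured in 7-day-old Arabidopsis seedlings of the ecotype Columbia that had been exposed, or not, to 30% deuterium oxide (D2O), water in which deuterium takes the place of hydrogen. The 15 arrays fell into 5 groups of 3 biological replicates. H2O seedlings grew on control medium and D2O seedlings on medium with 30% D2O. HH seedlings were moved from H2O medium to fresh H2O medium, HD seedlings from H2O medium to medium with D2O, and DH seedlings from D2O medium back to H2O medium, each for 4 h. The deposited values are log2 expression values per probe set, and every level below is on that scale as mean ± SD of 3 arrays, with changes as log2 differences between group means. Array medians lay between 7.58 and 7.70. Correlations across probe sets were 0.990 to 0.998 between arrays of the same group and 0.956 to 0.992 between arrays of different groups. The mean difference between 3' and 5' control probe sets, a sign of RNA integrity, was 0.90 ± 0.06 in H2O, 0.89 ± 0.09 in D2O, 0.98 ± 0.13 in HH, 1.03 ± 0.17 in HD and 0.98 ± 0.11 in DH. It did not differ detectably in any of the 5 pairwise comparisons (two-sided exact permutation tests, raw p from 0.4 to 0.9, adjusted p = 0.9 in each); with 3 arrays against 3 such a test cannot go below 0.1.

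After growth on D2O for 7 days, the long-term exposure of the study's design, the abscisic acid, touch, unfolded protein response and root hair lists were called higher and that of the nuclear photosynthesis genes lower. Called in that direction were 2 of 5, 1 of 4, 2 of 4, 0 of 3 and 3 of 10 members, and with an estimated correlation none of the 5 lists was called (adjusted p from 0.0943 to 0.389). OSM34 (AT4G11650), an osmotin-like protein of the pathogenesis-related class, rose from 8.13 ± 0.37 in H2O to 10.76 ± 0.24 in D2O, a log2 change of 2.63 (SE 0.20, adjusted p = 8.46e-07). The other 9 of the 10 largest rises lay between 1.85 and 2.27. They included AT5G14650, a polygalacturonase-like protein (2.27, SE 0.18, adjusted p = 1.06e-06), AT2G37870, a lipid transfer protein (2.00, SE 0.11, adjusted p = 5.18e-08), and ATPMEPCRB (AT4G02330), a pectin methylesterase (1.97, SE 0.20, adjusted p = 1.40e-05). The largest fall was in AT5G37990, from 9.23 ± 0.11 to 6.602 ± 0.28 (-2.62, SE 0.14, adjusted p = 5.18e-08). AT1G66100, a thionin, fell by 2.51 (SE 0.22, adjusted p = 3.47e-06), and AT1G64500, a glutaredoxin family protein, fell by 1.62 (SE 0.10, adjusted p = 1.44e-07).

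Among the gene lists, the 10 measured photosynthesis transcripts of the nucleus lay lower in D2O (median -0.20, adjusted p = 1.01e-06; adjusted p = 0.0943 with an estimated correlation). Of these 10, 3 fell over all probe sets tested and 9 when adjusted over the list alone. The 3 were LHCB4.2 (AT3G08940), a light-harvesting antenna protein of photosystem II, from 13.30 ± 0.12 to 11.97 ± 0.10 (fell by 1.34, SE 0.09, adjusted p = 2.11e-07), PSAN (AT5G64040) of photosystem I (fell by 0.74) and PSBY, a photosystem II protein (fell by 0.45). CHLM (AT4G25080), a methyltransferase of chlorophyll synthesis, fell by 0.53, whereas PORB (AT4G27440), a protochlorophyllide oxidoreductase, rose by 0.57. Abscisic acid and dehydration transcripts lay higher (adjusted p = 0.00132; adjusted p = 0.0943 with an estimated correlation). Of 5 members 2 rose, both over all probe sets tested and adjusted over the list alone, among them COR47 (AT1G20440), a dehydrin, by 0.47 (SE 0.09, adjusted p = 0.00188). The touch and rapid stress list lay higher (adjusted p = 0.0178; adjusted p = 0.0943 with an estimated correlation). By either count 1 of its 4 members rose, WRKY53 (AT4G23810), a senescence-related transcription factor, from 6.56 ± 0.09 to 8.34 ± 0.37 (1.78, SE 0.15, adjusted p = 2.57e-06). The unfolded protein response of the endoplasmic reticulum was called higher as a list (adjusted p = 0.0270; adjusted p = 0.294 with an estimated correlation). Up by either count were 2 of its 4 members, BZIP60 (0.60, SE 0.16, adjusted p = 0.0222) and ATERDJ3B (0.46, SE 0.11, adjusted p = 0.0163), a transcription factor and a chaperone of that response. Root hair transcripts were called higher as a list (adjusted p = 0.0270; adjusted p = 0.389 with an estimated correlation), with 0 of 3 members past the threshold over all probe sets and 3 adjusted over the list alone. Among lists with fewer than 3 measured members, GSTU25, a glutathione transferase, rose by 0.64, SAG101, a defence regulator, by 0.73, and GI, a clock component, by 0.85.

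In this comparison 1320 probe sets were higher and 1216 lower among 22746 tested (limma, adjusted p under 0.05), 170 and 101 of them by at least 2-fold; of all tested, 5540 (24.4%) had groups that did not overlap, where chance gives 10%. Fitted to these 6 arrays alone, the counts were 690 and 664. The touch list lost its call without H2O replicate 1 (adjusted p = 0.0553), root hair without H2O replicate 2 (0.107) or D2O replicate 1 (0.0882) and the unfolded protein response without D2O replicate 1 (0.0882), and single calls were lost by BZIP60 without H2O replicate 1 or 2, by ATERDJ3B without H2O replicate 3 or D2O replicate 1, and by GI without H2O replicate 1 or 3 or D2O replicate 2.

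**Figure D1:**
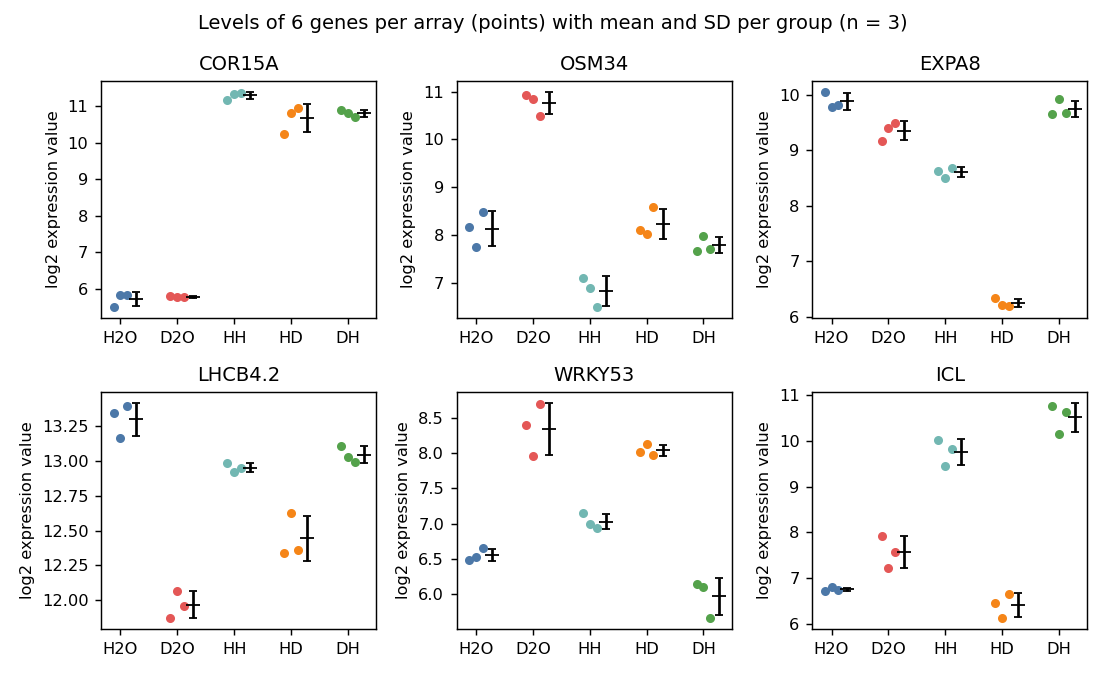
Log2 expression values of COR15A, OSM34, EXPA8, LHCB4.2, WRKY53 and ICL in the 15 arrays by group, with points for arrays and bars for the mean and SD of 3 arrays; these 6 genes were chosen for the plot after their values had been seen. OSM34 had its highest mean in D2O (10.76 ± 0.24), EXPA8 its lowest in HD (6.25 ± 0.08), and ICL lay at 9.76 ± 0.28 in HH against 6.41 ± 0.26 in HD and 6.76 ± 0.04 in H2O.

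After exposure to D2O for 4 h, compared with an equal move to H2O medium, the touch, flavonoid and heat shock lists were called higher and those of wall expansion enzymes, tubulins, cell division and photosynthesis lower. In these directions 4 of 4, 3 of 3, 6 of 6, 7 of 11 (with 1 in the other), 5 of 9, 2 of 3 and 3 of 10 members changed, and with an estimated correlation none of the 7 lists was called (adjusted p from 0.0739 to 0.364). AT2G37870, the lipid transfer protein that was also higher after growth on D2O, rose from 7.78 ± 0.06 in HH to 11.44 ± 0.06 in HD (3.66, SE 0.11, adjusted p = 1.07e-11). PRX52 (AT5G05340), a class III peroxidase, rose by 3.45 (SE 0.16, adjusted p = 1.32e-09) and AT2G43590, a chitinase family protein, by 2.83 (SE 0.12, adjusted p = 3.78e-10); the other 7 of the 10 largest rises lay between 2.53 and 3.05. AT1G66800 fell from 9.69 ± 0.09 to 5.85 ± 0.18 (-3.85, SE 0.11, adjusted p = 1.02e-11). ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle and the measured member of the seed reserve list, fell by 3.35 (SE 0.19, adjusted p = 9.86e-09), and the other 8 of the 10 largest falls lay between -2.52 and -3.54. In unmoved H2O seedlings AT2G37870 (7.68 ± 0.15) and PRX52 (6.14 ± 0.12) lay near their level in HH, whereas AT2G43590 (11.60 ± 0.10 in H2O, 8.69 ± 0.09 in HH and 11.52 ± 0.15 in HD), AT1G66800 (6.17 ± 0.10 in H2O) and ICL (6.76 ± 0.04 in H2O, 9.76 ± 0.28 in HH and 6.41 ± 0.26 in HD) lay nearer to their level in HD, so that HH was the group apart.

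Transcripts of expansins and xyloglucan-modifying enzymes, which loosen and remodel the cell wall, lay lower in HD (median -0.69, adjusted p = 0.00538; adjusted p = 0.337 with an estimated correlation). Of 11 members 7 fell and 1 rose over all probe sets tested, and 7 fell and 2 rose adjusted over the list alone. EXPA8 (AT2G40610) fell from 8.61 ± 0.09 to 6.25 ± 0.08 (-2.36, SE 0.10, adjusted p = 6.67e-10), EXPB3 by 1.58, EXPA4 by 1.22 and XTH33 by 1.03. In contrast XTH18 rose by 0.97 (SE 0.17, adjusted p = 4.28e-04). Tubulin transcripts lay lower (adjusted p = 8.63e-04; adjusted p = 0.0833 with an estimated correlation). Down were 5 of 9, or 7 adjusted over the list alone, such as TUB5 (fell by 0.77, SE 0.07, adjusted p = 8.72e-07) and TUB6 (fell by 0.47). The cell division list lay lower (adjusted p = 0.0257; adjusted p = 0.337 with an estimated correlation). Of its 3 members 2 fell, or 3 adjusted over the list alone, among them PRL, a replication licensing factor (by 0.78), and AUR1, an Aurora kinase (by 0.37). All 6 measured heat shock and folding transcripts rose by either count (adjusted p = 0.00429; adjusted p = 0.0739 with an estimated correlation). Their changes ran from 0.37 for AT1G53540, a small heat shock protein, and 0.62 for ATHSP22.0 to 1.33 for AT5G48570, an FKBP-type isomerase (SE 0.23, adjusted p = 3.72e-04). All 4 measured touch and rapid stress transcripts rose by either count (adjusted p = 0.00429; adjusted p = 0.0739 with an estimated correlation). They were the calmodulin-like CML37 (1.14) and CML38 (1.09), WRKY53 (1.01) and the zinc finger factor STZ (0.87). Without the lowest 40% of probe sets by mean, the heat shock and touch lists each had fewer than 3 members left and could not be tested. All 3 measured flavonoid transcripts rose by either count (adjusted p = 0.00429; adjusted p = 0.126 with an estimated correlation), namely DFR, dihydroflavonol reductase (0.98), UF3GT (0.97) and the anthocyanin glucosyltransferase AT4G14090 (1.47). Photosynthesis transcripts lay lower (adjusted p = 0.0299; adjusted p = 0.364 with an estimated correlation), with 3 of 10 down by either count, including LHCB4.2 by 0.51 and PSAN by 0.52.

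The 5 abscisic acid and dehydration transcripts all changed, 3 up and 2 down by either count, and the list as a whole was not called (adjusted p = 0.388). LTI30, a dehydrin, rose by 1.40 (SE 0.08, adjusted p = 1.51e-08) and COR15B fell by 1.38 (SE 0.13, adjusted p = 1.23e-06). GSTU25 rose by 1.99 (SE 0.14, adjusted p = 6.43e-08). PDF1.2, a jasmonate-responsive defensin, fell by 0.96, WES1, an auxin-conjugating enzyme, by 0.84, and BCAT4, an enzyme of methionine-derived glucosinolate synthesis, by 0.86. In HH over H2O, COR15B, PDF1.2 and BCAT4 rose by more than they fell here, so their means in HD still lay above those of unmoved H2O seedlings. RTE1, a regulator of ethylene receptors, rose by 0.38. The ribosomal protein transcript AT3G09200 fell by 0.25. MCCA, a subunit of a leucine-degrading carboxylase and the measured member of the sugar starvation list, fell by 0.66 (SE 0.19, adjusted p = 0.0164); its call ended without HH replicate 1 or HD replicate 1. In this comparison 3511 probe sets were higher and 3511 lower among 22746 tested (limma, adjusted p under 0.05), 536 and 275 of them by at least 2-fold; of all tested, 10235 (45.0%) had groups that did not overlap, where chance gives 10%. The call of the photosynthesis list ended without HD replicate 1 (adjusted p = 0.0827) and under cyclic loess normalization (0.138), and that of the cell division list without HD replicate 2 (0.0509).

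**Figure D2:**
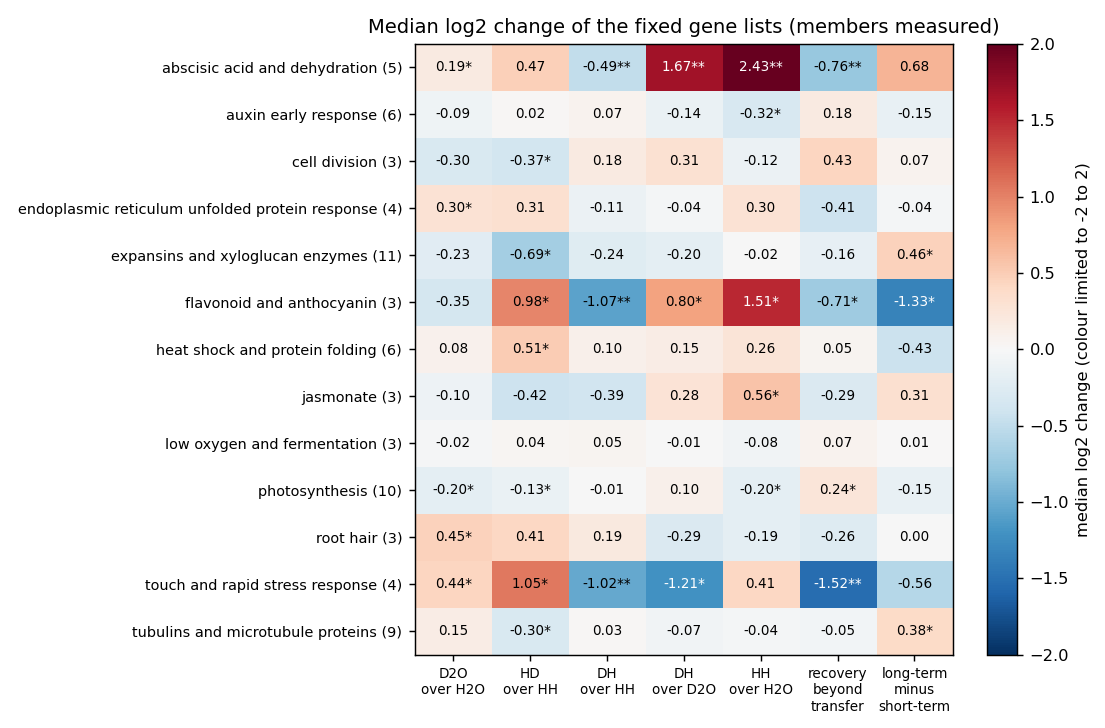
Median log2 change of the measured members of each gene list (lines of the grid, number of members in brackets) in the 7 comparisons (columns), with an asterisk where the list was called with the preset correlation and a pair where the call held with an estimated correlation. The abscisic acid list had its highest median in HH over H2O (2.43, 5 members). The calls that held with an estimated correlation were those of the abscisic acid, flavonoid and touch lists in DH over HH, of the abscisic acid list in DH over D2O and HH over H2O, and of the abscisic acid and touch lists in recovery beyond transfer.

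DH and HH seedlings were both moved to H2O medium 4 h before harvest, so that this comparison, which addresses recovery, matches the move and differs in the medium of growth. Of the 10 largest rises in DH, 9 were transcripts encoded in the plastid genome. The largest was psbB, a core antenna protein of photosystem II, from 8.87 ± 0.78 in HH to 10.65 ± 0.13 in DH (1.78, SE 0.46, adjusted p = 0.0209), and the other 9 lay between 1.21 and 1.65. Among them, ycf3, a photosystem I assembly factor, rose by 1.47 (SE 0.19, adjusted p = 1.39e-04), psaI, a photosystem I subunit, by 1.22 (SE 0.19, adjusted p = 5.54e-04), and AT1G49570, a peroxidase encoded in the nucleus, by 1.34 (SE 0.22, adjusted p = 9.17e-04). As groups of symbols tested by the same method, 20 of 33 plastid-encoded photosynthesis subunits rose (median 0.65, adjusted p = 1.17e-14; adjusted p = 0.131 with an estimated correlation). Of the plastid-encoded NDH subunits, 7 of 10 rose (adjusted p = 3.33e-06; adjusted p = 0.178 with an estimated correlation). Of the plastid-encoded polymerase subunits and ribosomal proteins, 16 of 19 rose (adjusted p = 3.27e-12; adjusted p = 0.131 with an estimated correlation). Among the 62 plastid-encoded transcripts in these groups 0 fell. By contrast, 0 of the 10 nuclear photosynthesis transcripts changed, also adjusted over the list alone (adjusted p = 0.944). The mean of the 62 plastid-encoded transcripts was 10.08 ± 0.23 in HH and 10.89 ± 0.20 in DH (difference 0.81, two-sided exact permutation p = 0.1, the smallest possible; adjusted p = 0.25). That of 16 mitochondrion-encoded transcripts was 6.55 ± 0.09 and 6.599 ± 0.05 (difference 0.05, exact permutation p = 0.5; adjusted p = 0.6).

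The touch, abscisic acid and flavonoid lists were called lower in DH than in HH, also with an estimated correlation, with 3 of 4, 4 of 5 and 3 of 3 members down. Among single genes, the largest fall was in AT4G17470, from 10.01 ± 0.26 to 7.30 ± 0.32 (-2.71, SE 0.17, adjusted p = 3.70e-07); TBL26, a protein of cell wall polysaccharide acetylation, fell by 1.83 (SE 0.16, adjusted p = 6.07e-06). The other 8 of the 10 largest falls included CYP71B23, a cytochrome P450 (fell by 1.65, SE 0.12, adjusted p = 1.22e-06), and the thionin AT1G66100. The touch and rapid stress list was called lower (adjusted p = 7.81e-05; adjusted p = 0.0187 with an estimated correlation). By either count 3 of its 4 members fell, STZ by 1.62 (SE 0.24, adjusted p = 4.78e-04), WRKY53 by 1.06 (SE 0.15, adjusted p = 4.04e-04) and CML38 by 0.99 (SE 0.13, adjusted p = 1.54e-04). The abscisic acid and dehydration list was called lower (adjusted p = 6.24e-05; adjusted p = 0.0284 with an estimated correlation). Of its 5 members 4 fell, or 5 adjusted over the list alone, among them LTI30 by 0.97 (SE 0.08, adjusted p = 5.31e-06) and COR15B by 0.61 (SE 0.13, adjusted p = 0.00639). All 3 flavonoid transcripts fell by either count (adjusted p = 7.81e-05; adjusted p = 0.0434 with an estimated correlation): DFR by 1.07, UF3GT by 0.73 and AT4G14090 by 1.18. EXPA8 rose by 1.14 (SE 0.10, adjusted p = 7.68e-06) and XTH20 fell by 0.93 (SE 0.16, adjusted p = 0.00115), and their list was not called (adjusted p = 0.366). In this comparison 971 probe sets were higher and 1666 lower among 22746 tested (limma, adjusted p under 0.05), 25 and 174 of them by at least 2-fold; of all tested, 8226 (36.2%) had groups that did not overlap, where chance gives 10%. The number higher moved with the arrays used: it was 538 to 616 with any 1 of the 6 arrays left out (538, and 1072 lower, without HH replicate 2), 1841 with these 6 arrays alone and 2550 with array weights, which also gave 2738 lower. The call of psbB, but not that of ycf3 or psaI, ended without HH replicate 2 or 3 or any 1 of the DH arrays.

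**Figure D3:**
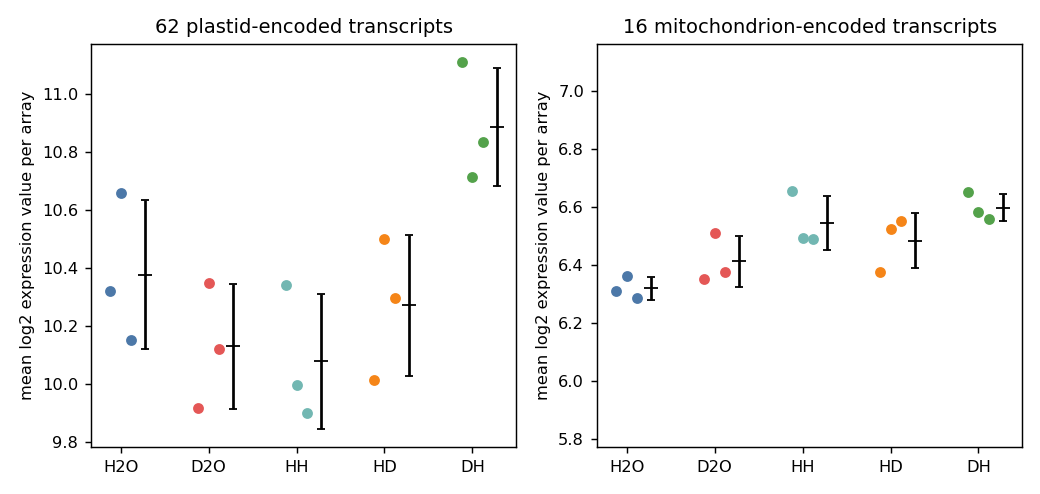
Mean log2 value of 62 plastid-encoded and of 16 mitochondrion-encoded transcripts in each array, by group, with the mean and SD of 3 arrays. The DH arrays lay between 10.71 and 11.11 for the plastid mean, above the HH arrays at 9.90 to 10.34.

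The direct comparison of DH with D2O holds the effect of the move as well as that of leaving D2O. Its largest change was in COR15A (AT2G42540), a cold- and dehydration-induced chloroplast protein, from 5.78 ± 0.02 in D2O to 10.80 ± 0.10 in DH (5.02, SE 0.14, adjusted p = 1.76e-11). AT2G38240, a dioxygenase, rose by 4.39 (SE 0.21, adjusted p = 1.94e-09), and AT1G66800, AT5G23840 and AT5G35940 rose by 3.74 to 3.79. AT5G14650 fell by 4.31 (SE 0.18, adjusted p = 4.35e-10), BHLH101 (AT5G04150), a transcription factor of iron deficiency, by 4.02 (SE 0.25, adjusted p = 2.57e-08), and the chitinase AT2G43590 by 3.61 (SE 0.12, adjusted p = 5.74e-11). Abscisic acid and dehydration transcripts lay higher in DH (adjusted p = 3.88e-05; adjusted p = 0.0498 with an estimated correlation). Up by either count were 4 of 5, including COR15B (1.67). All 3 flavonoid transcripts rose by either count (adjusted p = 0.0398; adjusted p = 0.313 with an estimated correlation), DFR by 0.96. The touch and rapid stress list lay lower (adjusted p = 0.0113; adjusted p = 0.0640 with an estimated correlation). Down by either count were 2 of its 4 members, WRKY53 by 2.37 (SE 0.15, adjusted p = 3.38e-08) and STZ by 2.01 (SE 0.24, adjusted p = 1.80e-05). Outside the lists that were called, LHCB4.2 rose by 1.08 (SE 0.09, adjusted p = 3.16e-07), ICL rose by 2.94 (SE 0.19, adjusted p = 3.61e-08) and GSTU25 fell by 2.09 (SE 0.14, adjusted p = 4.44e-08). In this comparison 3506 probe sets were higher and 3182 lower among 22746 tested (limma, adjusted p under 0.05), 247 and 451 of them by at least 2-fold; of all tested, 9556 (42.0%) had groups that did not overlap, where chance gives 10%. The call of the flavonoid list ended without D2O replicate 3 (adjusted p = 0.0668) or DH replicate 1 (0.0659).

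Moving seedlings between plates of the same H2O medium gave the background of the transfer itself. COR15A rose from 5.72 ± 0.20 in H2O to 11.29 ± 0.10 in HH (5.57, SE 0.14, adjusted p = 1.74e-12), the largest change among the named genes of the 5 pairwise comparisons, and JRG21 (AT3G55970), a jasmonate-regulated dioxygenase, rose by 4.44 (SE 0.12, adjusted p = 2.26e-12). BHLH101 fell by 3.40 (SE 0.25, adjusted p = 1.93e-07), AT3G12900, a coumarin hydroxylase, by 3.32 (SE 0.15, adjusted p = 6.91e-10) and AT2G43590 by 2.90 (SE 0.12, adjusted p = 2.02e-10). All 5 measured abscisic acid and dehydration transcripts rose by either count (median 2.43, adjusted p = 2.70e-12; adjusted p = 0.00201 with an estimated correlation), among them COR15B (2.43) and LTI30 (1.31). All 3 flavonoid transcripts rose by either count (adjusted p = 1.52e-04; adjusted p = 0.0705 with an estimated correlation), DFR by 1.68 (SE 0.19, adjusted p = 1.43e-05). The jasmonate list lay higher (adjusted p = 0.0317; adjusted p = 0.167 with an estimated correlation). By either count 2 of its 3 members rose, PDF1.2 by 1.12 (SE 0.20, adjusted p = 7.18e-04) and PDF1.2b by 0.56. Auxin early response transcripts lay lower (adjusted p = 0.0138; adjusted p = 0.0827 with an estimated correlation). Down were 4 of 6, or 5 adjusted over the list alone, including IAA29 by 0.76 and the homeobox factor HAT2 by 0.56. Photosynthesis transcripts lay lower in HH (adjusted p = 0.00686; adjusted p = 0.263 with an estimated correlation). Down were 6 of 10, or 8 adjusted over the list alone, among them LHCB4.2 by 0.35 and PSBY by 0.41. ICL rose by 3.004 (SE 0.19, adjusted p = 3.59e-08), BCAT4 by 1.40 and UGT74B1, a glucosinolate glucosyltransferase, by 1.01. PYK10, a root beta-glucosidase and the measured member of the root tissue list, rose by 0.20. That call ended with any 1 of the H2O arrays or HH replicate 1 or 2 left out. The low oxygen list was called in 0 of the 7 comparisons (adjusted p = 0.615 in DH over D2O, the lowest). In HH over H2O 1 of its 3 members fell by either count, AT3G10040, by 0.79, and that call ended without H2O replicate 3 or HH replicate 2 or 3. In this comparison 2483 probe sets were higher and 2961 lower among 22746 tested (limma, adjusted p under 0.05), 379 and 138 of them by at least 2-fold; of all tested, 9807 (43.1%) had groups that did not overlap, where chance gives 10%. The call of the jasmonate list ended without H2O replicate 1 (adjusted p = 0.0684).

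**Figure D4:**
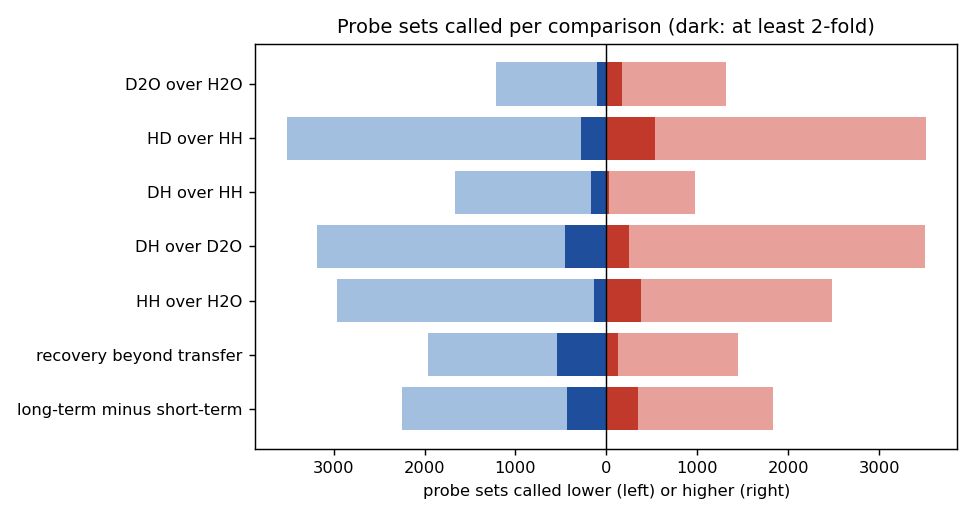
Numbers of probe sets higher and lower at adjusted p under 0.05 in each of the 7 comparisons (bars from 0), with those changed by at least 2-fold as the darker part. HD over HH had 3511 higher and 3511 lower, and D2O over H2O 1320 and 1216.

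Pairs of comparisons with no array in common were set side by side across probe sets, which are not independent replicates. Both comparisons of a pair used the same variance estimate per probe set, so overlaps can exceed the count by chance without a shared effect. Long-term and short-term exposure shared 673 probe sets called higher in both (203.8 by chance for independent lists) and 420 called lower in both (187.7 by chance); Pearson's r of the changes was 0.254 and Spearman's rho 0.225. Between D2O over H2O and DH over HH, 443 probe sets were higher in the first and lower in the second (96.7 by chance), and 186 were lower in both (89.1 by chance). A further 94 were lower in the first and higher in the second (51.9 by chance), and 61 were higher in both (56.3 by chance), with r -0.208 and rho -0.185. WRKY53 was among the 443, a transcript that rose by 1.78 in D2O and fell by 1.06 in DH relative to HH. Between DH over D2O and HH over H2O, 1170 were higher in both (382.7 by chance) and 1067 lower in both (414.2 by chance), with r 0.473 and rho 0.406. COR15A, AT2G38240, AT5G23840 and AT5G35940 were among the 5 largest rises, and BHLH101 and AT2G43590 among the 5 largest falls, of both.

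**Figure D5:**
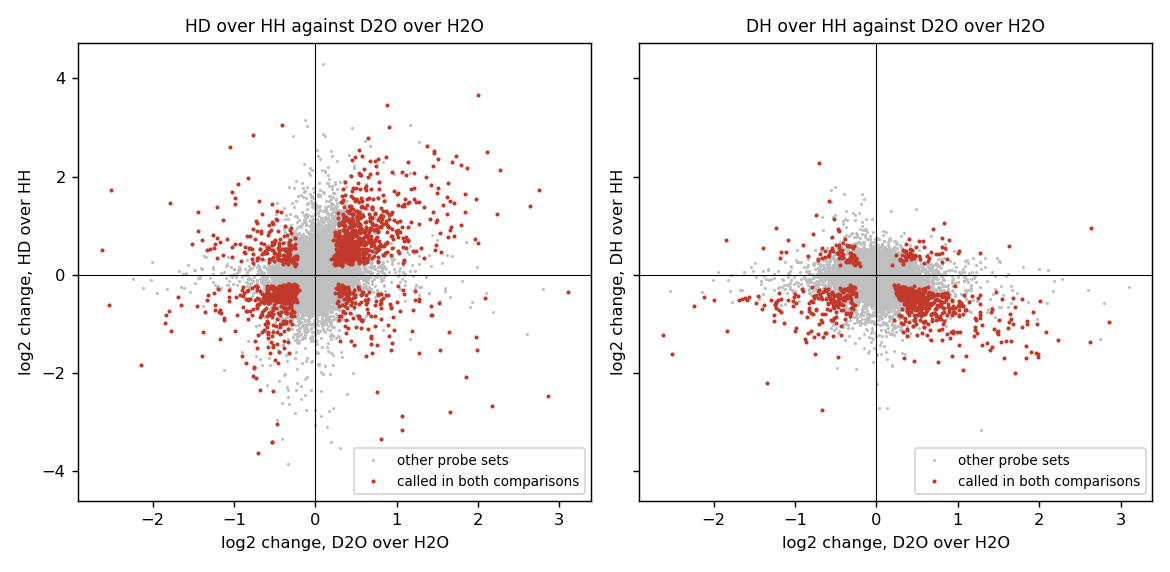
Log2 change of each probe set in HD over HH and in DH over HH (vertical axes) against D2O over H2O (horizontal axis), with probe sets called in both comparisons in red. Of these, 673 lie in the upper right and 420 in the lower left of the HD panel, and 443 in the lower right of the DH panel.

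Differences between effects were tested as interaction terms of the same fit. Recovery beyond transfer, the change from D2O to DH minus that from H2O to HH, had 1443 probe sets higher and 1957 lower, and the long-term effect minus the short-term effect had 1829 higher and 2252 lower, of 22746 tested. Tubulin transcripts differed between the exposures (adjusted p = 2.60e-04; adjusted p = 0.153 with an estimated correlation), with TUB5 rising by 0.42 after growth on D2O and falling by 0.77 in the short exposure. The tubulin list itself was not called in D2O over H2O (camera, adjusted p = 0.138), where 2 of 9 members rose and 1 fell.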

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

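The results here are differences between effects, each tested as an interaction term over 12 arrays; among the tests named below, those of RNA degradation and of organelle RNA labelling were chosen only after the result was seen. For recovery beyond transfer, that is the change from D2O to DH minus the change from H2O to HH, 1443 probe sets were higher and 1957 lower. The 12 arrays were put into 4 groups of 3 in 100 seeded ways, the real one included. Of these 1 gave as many calls, the real one with 3400, and the highest of the others gave 1598. The regroupings mixed arrays of groups that also differ in the pairwise comparisons, and they took no account of replicate numbers. They therefore speak only against arrays without any group differences and cannot decide whether the interaction alone arose by chance. The highest differences of named genes were psbB 2.28 (SE 0.65), psbT 2.05 (SE 0.47), ycf3 2.04 (SE 0.27), psbD 1.84 (SE 0.52) and rpl20 1.82 (SE 0.48), all encoded in the plastid. Among these, psbT and ycf3 kept their call under every alternative tried for single genes. Those of psbB (1.77 to 2.73 over the alternatives), psbD (1.49 to 2.23) and rpl20 (1.49 to 2.298) ended without H2O replicate 2 or HH replicate 2. They also ended without D2O replicate 1 or 3 or DH replicate 2 (psbB, psbD), HH replicate 3 or DH replicate 1 (psbB, rpl20) or DH replicate 3 (psbD), without D2O replicate 1 and HD replicate 1 together (psbB), and with a variance trend and robust moderation (psbB, psbD). The lowest were AT5G52760 -3.59 (SE 0.53), AT2G18690 -3.53 (SE 0.31), AT4G12500 -3.30 (SE 0.28), an EARLI1-like protein, AT2G43620 -2.998 (SE 0.16), a chitinase family protein, and ATPMEPCRB -2.97 (SE 0.29), a pectin methylesterase.

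Touch and rapid stress transcripts (adjusted p = 4.99e-05; adjusted p = 0.0120 with an estimated correlation) and abscisic acid and dehydration transcripts (adjusted p = 2.14e-06; adjusted p = 0.0120 with an estimated correlation) lay lower in this term than other transcripts. Called lower were 3 of 4 and 4 of 5 members, or 3 and 5 adjusted over the list alone. Flavonoid transcripts also lay lower (adjusted p = 0.0374; adjusted p = 0.299 with an estimated correlation; 1 of 3 members, or 3 adjusted over the list alone), a call that ended without H2O replicate 1 (0.0645), D2O replicate 2 (0.0742), HH replicate 1 (0.0600) or DH replicate 3 (0.0637). Nuclear photosynthesis transcripts lay higher (adjusted p = 3.33e-04; adjusted p = 0.299 with an estimated correlation; 4 of 10, or 5 adjusted over the list alone). Among groups of symbols, 15 of 47 UDP-glycosyltransferases were lower and 3 higher (adjusted p = 1.28e-04; adjusted p = 0.284 with an estimated correlation). Of the calmodulin-like proteins 3 of 7 were lower (adjusted p = 0.0179; adjusted p = 0.284 with an estimated correlation, and 0.302 without dim probe sets), and 4 of 9 U-box ubiquitin ligases were lower (adjusted p = 0.0444; adjusted p = 0.284 with an estimated correlation, 0.0675 without dim probe sets, 0.0569 under quantile normalization, 0.0548 under cyclic loess, 0.0781 with array weights, 0.0691 without H2O replicate 2, 0.0574 without D2O replicate 1, 0.0524 without D2O replicate 3, 0.0641 without HH replicate 2, 0.0543 without DH replicate 2 and 0.0524 without D2O replicate 1 and HD replicate 1). Plastid-encoded transcripts were higher: 21 of 33 photosynthesis subunits (adjusted p = 8.29e-12; adjusted p = 0.284 with an estimated correlation) and 6 of 10 NDH subunits (adjusted p = 9.63e-05; adjusted p = 0.364 with an estimated correlation). Of the plastid-encoded polymerase subunits and ribosomal proteins, 13 of 19 were higher (adjusted p = 1.48e-08; adjusted p = 0.303 with an estimated correlation).

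For the long-term effect minus the short-term effect, 1829 probe sets were higher and 2252 lower. In 100 seeded regroupings, 1 gave as many calls, the real one with 4081, and the highest of the others gave 1855. The limit given above for such regroupings holds here too. The highest differences were AT1G19960 4.45 (SE 0.31), ICL 4.16 (SE 0.27), AT5G23840 3.84 (SE 0.28), AT5G35940 3.59 (SE 0.29) and AT1G66800 3.51 (SE 0.15). The lowest were AT1G66100 -4.25 (SE 0.32), AT3G58060 -3.65 (SE 0.22), a cation efflux family protein, AT3G12900 -3.25 (SE 0.21), AT5G37990 -3.12 (SE 0.20) and AT2G43590 -3.10 (SE 0.16). The term contains HH minus H2O, and ICL, AT5G23840, AT5G35940, AT1G66800, AT3G12900 and AT2G43590 differed strongly between HH and H2O. Their values thus do not show by themselves that both exposures acted in opposite ways. AT1G66100 and AT5G37990 were instead among the largest falls in D2O over H2O. Tubulins lay higher in this term (adjusted p = 2.60e-04; adjusted p = 0.153 with an estimated correlation; 5 of 9 members higher, or 7 adjusted over the list alone). Expansins with xyloglucan enzymes did as well (adjusted p = 0.00415; adjusted p = 0.471 with an estimated correlation; 5 of 11 higher and 1 lower by either count). Flavonoid transcripts lay lower (adjusted p = 0.00192; adjusted p = 0.153 with an estimated correlation; 3 of 3 by either count). Among groups of symbols, expansins and expansin-like proteins had 6 of 18 members higher and 1 lower (adjusted p = 0.0313; adjusted p = 0.808 with an estimated correlation, 0.0589 without H2O replicate 2, 0.106 without D2O replicate 1, 0.0832 without HH replicate 3, 0.121 without HD replicate 2 and 0.119 without HD replicate 3). Of the U-box ubiquitin ligases 3 of 9 were lower (adjusted p = 0.0189; adjusted p = 0.154 with an estimated correlation). Lower were also 6 of 33 plastid-encoded photosynthesis subunits (adjusted p = 0.0251; adjusted p = 0.808 with an estimated correlation, 0.0633 with array weights, 0.167 by fry in one direction, 0.0518 without H2O replicate 1, 0.128 without H2O replicate 2, 0.151 without D2O replicate 1, 0.132 without HH replicate 3 and 0.190 without HD replicate 2) and 3 of 19 plastid-encoded polymerase subunits and ribosomal proteins (adjusted p = 0.0189; adjusted p = 0.808 with an estimated correlation, 0.0699 with array weights, 0.125 by fry in one direction, 0.0519 by fry in either direction, 0.119 without H2O replicate 2, 0.0919 without D2O replicate 1, 0.0832 without HH replicate 3 and 0.121 without HD replicate 2).

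Plastid-encoded transcripts in the first of these terms join a shift of the 62-transcript mean of 0.81 ± 0.19 (SE) in DH over HH, which is weighed here, with one of -0.25 in D2O over H2O. Unmoved H2O seedlings had a mean of 10.38 ± 0.26 (SD), between HH (10.08 ± 0.23) and DH (10.89 ± 0.20). The difference of HH over H2O was -0.30 (two-sided exact permutation p = 0.3), so the shift also holds a lower mean in HH. RNA degradation is argued against, since the 3' minus 5' difference was 0.00563 ± 0.10 higher in DH than in HH, which at its slope within groups (1.29 ± 0.50) accounts for 0.00723 ± 0.12 of the shift, and so is a single array, because the shift was at least 0.70 with any 1 of the 6 arrays left out. More labelling of organelle RNA in general is argued against by the 16 mitochondrion-encoded transcripts, which shifted by 0.0523 ± 0.06, although 2 of them rose, among them ccb382, the brightest, by 0.73. Most of them were dim, but dim plastid-encoded transcripts did shift. Among those with a mean below 7.67 in H2O and D2O, the 7 plastid-encoded ones moved by 1.15 ± 0.36 and the 15 mitochondrion-encoded ones by 0.00733 ± 0.07. The argument against more labelling thus covers dim transcripts only, and the bright ccb382 went the other way. A higher level of plastid transcripts in DH than in HH may therefore be a biological difference. Changes in the polyadenylation, priming or decay of plastid RNA alone were not tested and stay open.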

How the results depend on the processing

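The alternatives that leave out D2O replicate 1 and HD replicate 1 together and that put a replicate block within H2O and D2O were chosen after seeing the data; the others were fixed earlier. No result that was followed changed direction. Counts of calls stayed within 1.5 times in 207 of 260 values, and list calls in 529 of 589 and calls of symbol groups in 515 of 604 kept their side of the threshold. Of the single genes, 596 of 816 calls held under every alternative tried for them. The 2-fold minimum and adjusted p under 0.01 were applied to counts only. Only called genes were followed, a restriction set after a first run had shown sign changes in uncalled list members near 0. Such members can change sign, so the lack of reversals among single genes covers called genes only. Fry in either direction gives no direction and could not show a reversal. No setting turned on signal over background, which the deposited values do not give; transcripts near the low end of the scale are the least certain. The alternative for linear values was not run, since the values are log2. Where a list had fewer than 3 members left without dim probe sets, it gave no value there, as in 8 of 31 list results. These were every followed result of the touch list, heat shock in HD over HH, jasmonate in HH over H2O and low oxygen in DH over D2O. Those results could not be checked on brighter probe sets alone. Except where the number of probe sets or arrays falls by construction, the cause of a lost call was not tested.

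Replicate numbers went together in D2O over H2O but not in the other pairwise comparisons, and a replicate block within H2O and D2O gave 1532 higher and 1382 lower there. Of the calls of lists, symbol groups and single genes followed in that comparison it ended that of AUR2 and changed no other. Over all groups, 8 of 30 same-numbered pairs had a residual correlation above 0.1, 7 of them among the 9 pairs of H2O, D2O and HD, and 6 of 15 arrays correlated best with their own number. The mean residual correlation was 0.0255 for same-numbered pairs and -0.0128 for other pairs, so pairing over all groups is not apparent. With the number as a block in all groups, the counts higher and lower were 1291 and 1183 in D2O over H2O, 3470 and 3547 in HD over HH, 911 and 1654 in DH over HH, 3589 and 3180 in DH over D2O, 2480 and 2856 in HH over H2O, 1383 and 1925 in recovery beyond transfer and 1799 and 2211 in long-term minus short-term, and no list call changed.

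Array weights gave 2550 higher and 2738 lower in DH over HH, 2664 higher in recovery beyond transfer. The arrays of the groups compared alone gave 690 higher and 664 lower in D2O over H2O, 1841 higher in DH over HH. Probe sets with 1 gene alone, fewer by construction, gave 571 higher and 576 lower in D2O over H2O, 1884 higher and 1862 lower in HD over HH, 516 higher and 779 lower in DH over HH, 1927 higher and 1715 lower in DH over D2O, 1212 higher and 1663 lower in HH over H2O, 701 higher and 873 lower in recovery beyond transfer, 910 higher and 1178 lower in long-term minus short-term. Changes of at least 2-fold numbered 170 higher and 101 lower in D2O over H2O, 536 higher and 275 lower in HD over HH, 25 higher and 174 lower in DH over HH, 247 higher and 451 lower in DH over D2O, 379 higher and 138 lower in HH over H2O, 127 higher and 547 lower in recovery beyond transfer, 348 higher and 432 lower in long-term minus short-term. At adjusted p under 0.01 there were 755 higher and 641 lower in D2O over H2O, 2091 lower in HD over HH, 344 higher and 979 lower in DH over HH, 2114 higher in DH over D2O, 1517 higher and 1631 lower in HH over H2O, 574 higher and 1229 lower in recovery beyond transfer, 985 higher and 1327 lower in long-term minus short-term. With 1 array left out, DH over HH had 538 to 616 higher, all 6 arrays taking the count below its limit, and 1072 to 1360 lower. Without D2O replicate 1 and HD replicate 1 there were 1053 higher and 1023 lower in D2O over H2O, 3341 and 2991 in HD over HH, 3542 and 3021 in DH over D2O, 1421 and 1875 in recovery beyond transfer and 1561 and 2183 in long-term minus short-term.

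Calls of symbol groups that were lost stand beside those results; list calls lost are given as adjusted p. Without dim probe sets they were unfolded protein response 0.0654 and root hair 0.0654 in D2O over H2O, cell division 0.0746, expansins 0.0558 and photosynthesis 0.0854 in HD over HH, flavonoid 0.102 in DH over D2O, auxin 0.125 in HH over H2O, flavonoid 0.0783 in recovery beyond transfer, expansins 0.0730 in long-term minus short-term. Cyclic loess normalization gave root hair 0.0511 in D2O over H2O, photosynthesis 0.138 in HD over HH, and quantile normalization ended none. An estimated correlation gave abscisic acid 0.0943, unfolded protein response 0.294, photosynthesis 0.0943, root hair 0.389 and touch 0.0943 in D2O over H2O, cell division 0.337, expansins 0.337, flavonoid 0.126, heat shock 0.0739, photosynthesis 0.364, touch 0.0739 and tubulins 0.0833 in HD over HH, flavonoid 0.313 and touch 0.0640 in DH over D2O, auxin 0.0827, flavonoid 0.0705, jasmonate 0.167 and photosynthesis 0.263 in HH over H2O, flavonoid 0.299 and photosynthesis 0.299 in recovery beyond transfer, expansins 0.471, flavonoid 0.153 and tubulins 0.153 in long-term minus short-term. Fry in one direction gave root hair 0.0680 in D2O over H2O, and in either direction unfolded protein response 0.428 and root hair 0.573 in D2O over H2O, cell division 0.165 and flavonoid 0.108 in HD over HH, flavonoid 0.206 in DH over HH, flavonoid 0.252 in DH over D2O, flavonoid 0.0759 and jasmonate 0.173 in HH over H2O, flavonoid 0.462 in recovery beyond transfer, flavonoid 0.136 in long-term minus short-term. With arrays left out, the ranges were 0.00468 to 0.0553 for touch in D2O over H2O (lost without H2O replicate 1), 0.0140 to 0.107 for root hair (H2O replicate 2 or D2O replicate 1), and 0.0117 to 0.108 for the unfolded protein response (D2O replicate 1, also together with HD replicate 1). In the other comparisons they were 0.0176 to 0.0509 for cell division in HD over HH (HD replicate 2), 0.0178 to 0.0827 for photosynthesis (HD replicate 1, also together with D2O replicate 1), 0.0311 to 0.0668 for flavonoid in DH over D2O (D2O replicate 3 or DH replicate 1), 0.0219 to 0.0684 for jasmonate in HH over H2O (H2O replicate 1) and 0.0164 to 0.0742 for flavonoid in recovery beyond transfer (H2O replicate 1, D2O replicate 2, HH replicate 1 or DH replicate 3).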

Other observations

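Among the tests named below, that of a smaller transfer response was chosen only after the result was seen; the members of symbol groups named here were picked after their values were seen. Beyond the gene lists of the report, families of genes named by symbol were tested with the same method. In DH over HH, 4 of 14 glutathione transferases, enzymes of detoxification, were lower (adjusted p = 0.00119; adjusted p = 0.131 with an estimated correlation), such as GSTU16, which fell by 0.84 (SE 0.14, adjusted p = 0.00102). Of the UDP-glycosyltransferases 11 of 47 were lower and 2 higher (adjusted p = 0.00128; adjusted p = 0.178 with an estimated correlation). Among them were UGT78D1, a flavonol rhamnosyltransferase, which fell by 1.15 (SE 0.16, adjusted p = 3.02e-04), and UGT84A1, which fell by 1.08 (SE 0.22, adjusted p = 0.00437). In the CYP71B subfamily of cytochromes P450, 6 of 19 were lower (adjusted p = 0.00684; adjusted p = 0.170 with an estimated correlation), CYP71B23 at -1.65 and CYP71B24 at -1.13. Of the U-box ubiquitin ligases, 4 of 9 were lower (adjusted p = 0.00147; adjusted p = 0.0960 with an estimated correlation), with PUB23, a regulator of stress signalling, at -0.97 (SE 0.07, adjusted p = 2.00e-06) and PUB24 at -0.61. In HD over HH, where that family was not called (adjusted p = 0.0655), PUB23 rose by 2.18 (SE 0.07, adjusted p = 6.98e-11) and PUB22 by 1.47 (SE 0.10, adjusted p = 4.45e-08). Calmodulin-like proteins (adjusted p = 0.0227; adjusted p = 0.131 with an estimated correlation, 0.274 without dim probe sets and 0.0504 without DH replicate 1; 3 of 7 lower) and beta-glucosidases (adjusted p = 0.0227; adjusted p = 0.131 with an estimated correlation, 0.0561 with array weights and 0.0743 without DH replicate 2; 2 of 20 lower) also lay lower in DH over HH. Nuclear RNA polymerase subunits lay higher there as a group (adjusted p = 0.0227; adjusted p = 0.186 with an estimated correlation, 0.0556 without dim probe sets and 0.0749 without HH replicate 1) with 0 of 12 called.

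Transcripts of the ATG8 family, ubiquitin-like proteins of autophagosome formation, fell from D2O to DH in 7 of 9 members (adjusted p = 0.00156; adjusted p = 0.376 with an estimated correlation). ATG8E fell by 0.71 (SE 0.17, adjusted p = 0.00536), APG8A by 0.69 and ATG8H by 0.67. ATG8H had risen by 0.52 in D2O over H2O (SE 0.10, adjusted p = 0.00395), where the family was not called (camera, adjusted p = 0.0661). In DH over HH, which matches the move, 0 of 9 members were called (camera, adjusted p = 0.532). The family was not called in recovery beyond transfer either, so its fall cannot be assigned to leaving D2O rather than to the move. From D2O to DH, nuclear RNA polymerase subunits rose in 4 of 12 members (adjusted p = 0.0212; adjusted p = 0.376 with an estimated correlation, and 0.0723 without dim probe sets). NRPA2 and NRPA1, subunits of RNA polymerase I, were up by 1.14 (SE 0.20, adjusted p = 4.71e-04) and 1.12 (SE 0.18, adjusted p = 2.89e-04). Plastid-encoded photosynthesis subunits rose in 20 of 33 members (adjusted p = 1.09e-06; adjusted p = 0.376 with an estimated correlation), and polymerase subunits and ribosomal proteins in 9 of 19 (adjusted p = 0.00170; adjusted p = 0.497 with an estimated correlation). NDH subunits rose in 8 of 10 (adjusted p = 0.00932; adjusted p = 0.497 with an estimated correlation, and 0.0709 without DH replicate 1). After the move between plates of H2O medium, 3 of 5 methionine sulfoxide reductases, which repair oxidised methionine, rose (adjusted p = 0.00915; adjusted p = 0.289 with an estimated correlation), led by MSRB6 at 0.95 (SE 0.11, adjusted p = 1.91e-05). In the same comparison 14 of 47 UDP-glycosyltransferases rose and 3 fell (adjusted p = 0.0209; adjusted p = 0.621 with an estimated correlation, 0.221 without dim probe sets, 0.0528 with array weights, 0.0527 without H2O replicate 1 and 0.0750 without H2O replicate 2). Of the mitochondrion-encoded transcripts 7 of 16 rose and 1 fell (adjusted p = 0.0209; adjusted p = 0.621 with an estimated correlation, 0.0653 without dim probe sets and 0.0700 without HH replicate 1). Plastid-encoded photosynthesis subunits fell in 8 of 33 members there (adjusted p = 0.0284; adjusted p = 0.728 with an estimated correlation, 0.0572 under quantile normalization, 0.154 with array weights, 0.0909 by fry in one direction, 0.0796 without H2O replicate 1, 0.194 without H2O replicate 2 and 0.184 without HH replicate 3). Plastid-encoded polymerase subunits and ribosomal proteins fell in 8 of 19 (adjusted p = 0.00915; adjusted p = 0.707 with an estimated correlation, 0.0561 with array weights and 0.0750 without H2O replicate 2). In D2O over H2O, 2 of 33 plastid-encoded photosynthesis subunits fell (adjusted p = 0.0161; adjusted p = 0.752 with an estimated correlation, 0.212 by fry in one direction, 0.114 by fry in either direction, 0.130 without H2O replicate 1, 0.230 without H2O replicate 2, 0.109 without D2O replicate 1 and 0.118 without D2O replicate 1 and HD replicate 1).

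For the 247 probe sets that rose at least 2-fold from D2O to DH, a comparison that joins the move with leaving D2O, the median change in HD over HH was -0.61, with 144 called lower and 39 higher, while 181 were called higher in HH over H2O and 13 lower. HD replicate 1, which stood apart from its group, is argued against as the whole source, since the median was -0.45 without it. A further normalization left the median at -0.56 under cyclic loess, the setting that moved it most. As it started from RMA values, it cannot decide on an effect of the original normalization. A smaller response to the move in D2O would leave HD between H2O and HH. The median of HD minus H2O was 0.19 ± 0.05, which goes with it as a hypothesis found on the same data. Each ± in this paragraph is the SE of the difference of the set's mean over arrays, with variance pooled over groups, not that of the median. The 181 also called higher in HH over H2O had a median HD minus H2O of 0.51 ± 0.04 and a median HD minus HH of -0.64. Of the 451 probe sets that fell at least 2-fold from D2O to DH, 213 were called lower in HH over H2O and had a median HD minus H2O of 0.0275 ± 0.04. All 451 (56 called higher in HH over H2O) had one of 0.44 ± 0.06, above H2O, which a smaller response alone would not give. The subsets of 181 and 213 were picked with the same H2O arrays that these values use. A direct effect of D2O that reverses on its removal was not tested and stays open too, as no group was moved from D2O to D2O medium.

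In each pairwise comparison the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. Every other split mixes arrays of both groups, so that differences between the groups enter the variance. Low counts there follow wherever the groups differ and cannot decide on chance. The real split, counted as 1, gave 2536 calls in D2O over H2O against at most 2 for the 3 others that also part all 3 same-numbered pairs and 0 for the 6 that part 1, 7022 against 0 in HD over HH, 2637 against 1 in DH over HH, 6688 against 0 in DH over D2O and 5444 against 0 in HH over H2O.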
